A study of Sulfolobus acidocaldarius with 18 samples.

How the data were processed

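Messenger RNA was measured by sequencing in 18 libraries of the archaeon Sulfolobus acidocaldarius, which fall into 6 groups by strain and time. The wild type was a derivative of strain MW001 carrying pyrEF, the uracil synthesis genes used as a selection marker, and the mutant carried pyrEF inserted into tfb3, which encodes a general transcription factor. Each strain was sampled before and at 45 and 90 min after a UV dose of 100 J per square metre, with 3 replicates per group that the labels call biological replicates. Per the labels' protocols, cells grew at 75 °C in Brock medium at pH 3.5, ribosomal RNA was depleted, and strand-specific libraries were prepared before sequencing.

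The authors deposited raw read counts per locus for every library and 7 tables of pairwise comparisons. Per the submitters' processing notes, bcl2fastq 1.8.4, Bowtie2 and DESeq2 were used. The counting tool, its strand setting and the versions of Bowtie2 and DESeq2 were not given in the sources used here. The deposited comparison tables hold log2 fold changes, their standard errors and p-values from DESeq2, per the file headers; they were used only to set the authors' calls beside those computed here. In 4 of these 7 tables, 12 to 14 loci had a minus sign or decimal mark displaced into another cell, and these loci were left out of that comparison.

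The count table held 2223 loci, named by locus tag with coordinates on sequence NC_007181.1 of strain DSM639. Gene symbols came from the reference table of assembly ASM1228v1, in which 2191 loci matched by locus tag and 323 had a symbol; tfb3 was named from the labels. Product descriptions were not used here, so most loci appear by locus tag alone. Of the 267 loci named anywhere in the tables of results, 134 overlapped another locus, 34 of the overlaps being between opposite strands and none longer than 80 bp. Because the strand setting of the counting was not given, reads of overlapping loci on opposite strands cannot be told apart.

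Total counts ran from 2979253 to 9937693 per library. The default low-count filter of edgeR 4.0.16 removed 8 loci and left 2215. Counts were scaled by the trimmed mean of M values (TMM), with factors of 0.895 to 1.07, and tested by edgeR's quasi-likelihood F test in R 4.3.3, with 1 coefficient per group, all 18 libraries in the same fit and 12 residual degrees of freedom. The biological coefficient of variation was 12.6%. Levels are given as CPM, computed with edgeR's cpm function on the scaled library sizes, as mean ± SD over 3 replicates. Changes are log2 fold changes ± SE. The SE is not an output of edgeR's test. It was derived as the absolute log2 fold change divided by the square root of F, and the intervals given below rest on it. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, over all loci tested in that comparison. There were 11 comparisons: 9 between pairs of groups and 2 differences of responses, in which the change after UV in the wild type was subtracted from that in the mutant. Every replicate pair of a group differed by more than counting noise, with a chi-square per degree of freedom of 5.56 to 277, so no library was counted as a repeat of another. The highest values were those of WT1 replicate 3, 134 and 277, against 27.9 between WT1 replicates 1 and 2. This library also had the lowest TMM factor.

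Gene lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, again with a correlation estimated for each list, and with fry. Of 25 lists fixed before the data were examined, 10 had at least 3 tested members. The other 15 had fewer, 9 of them none. All of these but the S-layer list were text patterns written for product descriptions and matched here to gene symbols. The DNA repair, chromatin and CRISPR-associated lists were such patterns too, so they hold only genes with a symbol. From symbols, 12 more lists were written after the tables had been seen and before any model was fitted. The 22 lists were the UV-inducible pili, the DNA importer, cell division and segregation, DNA repair, chromatin proteins, archaellum, adhesive pili, CRISPR-associated genes, the neighbours of tfb3 and the pyrEF locus, and, by symbol, replication, repair, pyrimidine, purine, histidine and amino acid synthesis, ribosomal proteins, tRNA synthetases, chaperones and proteasome, respiration, cas genes and pentose transport. The pentose transport list held xylH, xylF and araD, and whether each encodes a transporter was not checked. Adjusted p-values of a list are over the 22 lists of that comparison.

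The sample groups, the test, the comparisons and the rule for naming genes were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls for each wild-type comparison with the state before UV and for each difference of responses, and the 5 largest each way elsewhere, among genes called with a mean of at least 10 CPM. Outside the differences of responses, the replicates of both groups also had to be fully separated. It added tfb3, every member of lists of up to 10 genes, the top 4 members of longer lists, and the TFB and Orc1/Cdc6 families. The alternatives tried were DESeq2 size factors, library totals as the only scaling, no low-count filter, the Wald test of DESeq2 1.42.0, a 2-fold minimum, fits of only the libraries compared, the replicate number as a block, and each library left out in turn.

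The tests were checked on simulated counts drawn from the real means and library sizes. For wild type 45 min after UV against before, 58.75% of genes changed by 0.5 on the log2 scale were called, 96.5% of those changed by 1 and 100% of those changed by 2, and 5 of 179 calls were of unchanged genes. For the difference of the 45 min responses these shares were 16.2%, 88.7% and 98.6%, with 6 of 149 calls of unchanged genes. None of 100 lists of unchanged genes had a camera p under 0.05. The simulated genes were drawn independently of each other, so this does not check camera on lists whose genes vary together. Each gene had the same mean in all groups, except for a small share of genes changed in 1 group. The gene tests were therefore not checked where a large share of genes changes or where 1 library departs from its group.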

Results

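Transcript levels were read from 18 RNA sequencing libraries of Sulfolobus acidocaldarius, a thermoacidophilic archaeon, from the wild type and from a tfb3 insertion mutant. Each strain was sampled before, 45 min after and 90 min after UV irradiation, with 3 biological replicates in each of the 6 groups. All libraries at 45 and 90 min came from irradiated cells, so every change against the state before UV, called a response below, also holds any effect of time and handling. Total counts per library were 5885119 to 8488155 in the wild type before UV, 5984741 to 9937693 at 45 min and 2979253 to 4886670 at 90 min. In the mutant they were 3873011 to 7787951, 6454500 to 9047553 and 3624560 to 5331071. The most abundant transcript in every library was slaA (Saci_2355), the major S-layer protein, with 4.15% to 9.89% of counts. On the first principal component (41.2% of the variance) the 6 libraries taken before UV lay apart from the 12 taken afterwards, and on the second (29.4%) the strains separated. Coordinates below are on NC_007181.1, counted from 1.

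The gene under study, tfb3 (Saci_0665, 526865 to 527452, forward strand), encodes a general transcription factor of the TFB family. In the wild type its level was 31.2, 35.0 and 29.8 CPM before UV, 158, 203 and 205 CPM at 45 min, and 339, 429 and 416 CPM at 90 min. In the mutant it was 52.0, 48.6 and 56.2 CPM before UV, 61.8, 70.5 and 62.0 CPM at 45 min, and 162, 163 and 142 CPM at 90 min. In the wild type tfb3 thus rose 5.88-fold by 45 min (log2 2.56 ± 0.13, edgeR adjusted p = 2.5e-10, n = 3) and 12.3-fold by 90 min (3.62 ± 0.13, adjusted p = 1.1e-12). In the mutant it rose by 0.31 ± 0.12 (adjusted p = 0.048) and 1.58 ± 0.12 (adjusted p = 1.9e-08). The mutant level lay above the wild-type level before UV (0.70 ± 0.13) and below it at 45 min (-1.55 ± 0.12) and 90 min (-1.34 ± 0.12). The labels describe an insertion and not a removal, and reads from either side of an insertion count for the same locus, so these values do not check the strain labels. The 45 min rise in the mutant was not called without Mut0 replicate 1 or 2 (0.31, 0.26) or without Mut1 replicate 1, 2 or 3 (0.34, 0.25, 0.34).

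**Figure D1:**
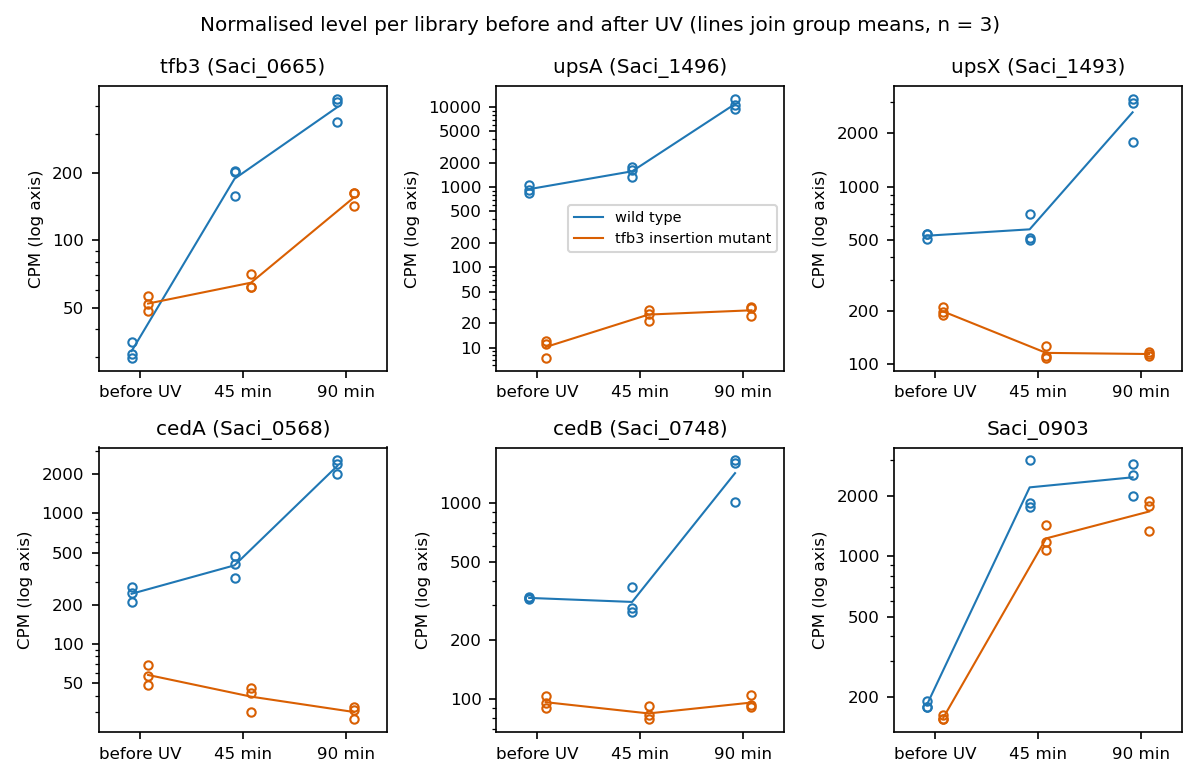
Normalised level (CPM, log axis) of tfb3, upsA, upsX, cedA, cedB and Saci_0903 in each library before, 45 min after and 90 min after UV in the wild type (blue) and the tfb3 insertion mutant (orange); points are libraries and lines join the means of 3 replicates. The ups and ced genes lie lower in the mutant at each time, and Saci_0903 lies higher after UV than before in both strains.

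Changes within 45 min after UV were examined first in the wild type. Saci_0903 (724282 to 725529), a member of the Orc1/Cdc6 family, rose 12.1-fold, from 182 ± 7.20 to 2196 ± 688 CPM (n = 3, edgeR adjusted p = 4.0e-10). Its neighbour Saci_0904 rose by 2.24 ± 0.25 on the log2 scale. Saci_1391 rose by 2.87 ± 0.16, arnR (Saci_1180), a regulator of motility genes, by 2.10 ± 0.16, and trxA (Saci_1823), a thioredoxin, by 1.84 ± 0.24. Of 9 purine synthesis genes 8 fell, with a median of -1.56. Among them were purC (-2.88 ± 0.15), purS (-2.71 ± 0.20), purT (-2.65 ± 0.17) and purL (-2.46 ± 0.22). Camera called the list with both correlations (adjusted p = 4.9e-12, and adjusted p = 0.032 with an estimated correlation). The exception was purE (0.02 ± 0.11), and the fall of purB (-0.29 ± 0.09) was not called without WT0 replicate 2 (-0.21). The endonuclease gene nucS (Saci_0200) fell by 1.93 ± 0.14.

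Other genes named by the rule at 45 min rose by 1.56 to 1.85 (Saci_0328, Saci_1003, Saci_1169, Saci_2075, Saci_0327 and Saci_2189). Others fell, with log2 changes of -2.69 for Saci_1701 and -2.54 for Saci_1290, and of -1.58 to -1.80 for Saci_0017, Saci_1766, Saci_0414, Saci_1797 and Saci_0598. Among the ups genes, which encode UV-inducible pili, upsA (0.74 ± 0.15) and Saci_1494 (0.73 ± 0.24) rose and the other 3 were not called. Of the ced genes, which encode a DNA importer, cedA1 (1.11 ± 0.17), cedA (0.73 ± 0.17) and cedA2 (0.67 ± 0.22) rose and cedB (-0.07 ± 0.15) was not called. The counts adjusted over the list alone were again 2 of 5 and 3 of 4, and camera called neither list (adjusted p = 0.43 and 0.21). The rise of Saci_1494 was not called without WT0 replicate 2 (0.72) or WT1 replicate 3 (0.31), nor that of cedA2 without WT0 replicate 1 (0.61), WT0 replicate 2 (0.58) or WT1 replicate 3 (0.49). By edgeR 509 genes were higher and 507 lower, 73 and 59 of them by at least 2-fold.

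At 90 min after UV the wild type expressed the ups and ced genes far above their level before UV. The 5 ups genes (1270248 to 1276756) all rose, with a median of 2.58. The pilin gene upsA (Saci_1496) went from 949 ± 102 to 10980 ± 1607 CPM, an 11.6-fold rise (3.53 ± 0.17, n = 3, edgeR adjusted p = 2.3e-11). Saci_1494 rose by 3.18 ± 0.25, upsF by 2.58 ± 0.26, upsX by 2.31 ± 0.17 and Saci_1497 by 1.03 ± 0.13. The 4 ced genes (cedA2, cedA and cedA1 at 460159 to 461352, cedB at 597891 to 599684) all rose, with a median of 3.20, by 3.13 ± 0.21, 3.26 ± 0.18, 3.51 ± 0.18 and 2.11 ± 0.15. Adjusted over the list alone the counts were again 5 of 5 and 4 of 4, and the calls of camera held with an estimated correlation (adjusted p = 0.026 for each list). Outside these lists, Saci_0478 rose by 3.99 ± 0.33 from a level of 1.54 CPM, Saci_0903 by 3.76 ± 0.20, Saci_1225 by 3.43 ± 0.14, Saci_1302 by 2.88 ± 0.18, Saci_0951 by 2.85 ± 0.16 and Saci_0667 by 2.71 ± 0.18.

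The genes for cell division and chromosome segregation fell at 90 min in the wild type. Of 8 genes, 7 were lower, also when adjusted over the list alone, with a median of -1.80. The level of cdvB (Saci_1373) went from 1606 ± 106 to 421 ± 60.9 CPM (-1.93 ± 0.14). In log2 terms cdvC fell by 1.74 ± 0.15 and cdvA by 1.29 ± 0.18, and Saci_0203 and Saci_0204, entered in the list as segregation genes, fell by 2.54 ± 0.17 and 2.14 ± 0.18. The gene cdvB3 (0.03 ± 0.11) was the exception, and the call of camera held (adjusted p = 0.026 with an estimated correlation). Purine synthesis genes stayed low, with 8 of 9 lower and a median of -1.79 (adjusted p = 0.026 with an estimated correlation). Without WT0 replicate 2 purB was not called (-0.27). Of 14 pyrimidine synthesis genes 9 fell, with a median of -0.46 (camera adjusted p = 0.011, and adjusted p = 0.032 with an estimated correlation). The call of pyrB was lost without WT0 replicate 2 (-0.34) or WT2 replicate 1 (-0.39). The largest falls outside these lists were of Saci_1701 (-3.38 ± 0.24), Saci_1193 (-3.06 ± 0.14), Saci_1290 (-2.98 ± 0.20), Saci_1012 (-2.85 ± 0.20), Saci_1189 (-2.75 ± 0.17) and Saci_0843 (-2.36 ± 0.16), and hjc (Saci_1741), a Holliday junction resolvase, fell by 2.35 ± 0.16. The other locus with the symbol hjc, Saci_1558, only went from 54.3 ± 4.13 to 44.4 ± 3.62 CPM.

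Camera called none of the other lists in the wild type at 90 min (adjusted p = 0.20 to 0.85). Of 9 DNA repair genes, radA, the recombinase, rose by 1.56 ± 0.16 and herA by 0.67 ± 0.11, while 3 fell; adjusted over the list alone these counts were the same. Of 7 archaellum genes 5 rose (also 5 adjusted over the list alone), and of 11 CRISPR-associated genes 3 rose (1 adjusted over the list alone). Of 5 adhesive pili genes 1 rose and 1 fell, and of 3 chromatin genes sac7d fell (-1.22 ± 0.18). Of 10 neighbours of tfb3 3 rose and 2 fell, and of 4 loci at pyrEF 3 fell. These last 4 counts were the same adjusted over the list alone. Among lists made from symbols, 4 of 14 replication genes rose and 7 fell (median -0.33, mean 0.02, camera direction down), and 2 of 14 repair genes rose and 5 fell. Of the others, 2 of 9 ribosomal protein genes rose and 1 fell, and 3 of 16 tRNA synthetase genes rose and 1 fell. Of 10 chaperone and proteasome genes 4 rose and 1 fell, of 24 amino acid synthesis genes 5 rose and 7 fell, and of 12 respiration genes 1 rose and 6 fell. Finally, 3 of 12 cas genes rose, 2 of 9 histidine synthesis genes fell and all 3 genes of the pentose list (xylH, xylF and araD) fell. By edgeR 587 genes were higher and 551 lower, 118 and 95 of them by at least 2-fold.

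Between 45 and 90 min the ups and ced genes rose and the division genes fell in the wild type. All 5 ups genes rose with a median of 2.36 (upsA 2.79 ± 0.16), all 4 ced genes with a median of 2.43 (cedA 2.53 ± 0.17), and 7 of 8 division genes fell with a median of -1.44 (Saci_0204 -1.86 ± 0.18). Adjusted over the list alone these counts were 5, 4 and 8, and camera called each list with an estimated correlation as well (adjusted p = 0.0013 for each). Saci_1225 rose by 3.00 ± 0.14 and Saci_0951 by 2.54 ± 0.16, while Saci_1012 (-2.03 ± 0.19), Saci_0743 (-2.03 ± 0.24), Saci_1295 (-1.99 ± 0.28) and Saci_0969 (-1.88 ± 0.23) fell. Of 11 CRISPR-associated genes 5 rose, or 6 adjusted over the list alone, including cas7d (1.10 ± 0.12). Camera's call of this list (adjusted p = 7.9e-05) was lost (adjusted p = 0.22 with an estimated correlation). So was that of the pyrimidine genes, of which 3 of 14 fell (adjusted p = 0.028, and adjusted p = 0.082 with an estimated correlation). By edgeR 210 genes were higher and 136 lower, or 128 and 88 in a fit of only the libraries compared. The fall of Saci_0451 (cdvB1/B2) was not called without WT2 replicate 3 (-0.63). The count of lower genes was 72 without WT2 replicate 3, and 78 without WT1 replicate 1 as well as without WT2 replicate 2.

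In the mutant, Saci_0903 rose 7.79-fold within 45 min (2.96 ± 0.20, n = 3, edgeR adjusted p = 5.6e-09), and Saci_0478 rose by 3.60 ± 0.35, Saci_1391 by 2.65 ± 0.16, Saci_2175 by 2.02 ± 0.31 and Saci_1003 by 1.99 ± 0.17. The purine genes were lower in 8 of 9 cases, with purS at -2.33 ± 0.21, purL at -2.06 ± 0.22 and purC at -1.92 ± 0.15. Camera called the list (adjusted p = 1.8e-06), and the call was lost (adjusted p = 0.25 with an estimated correlation). The calls of the histidine genes, 7 of 9 lower (adjusted p = 0.0062), and of the amino acid synthesis genes, 8 of 24 lower and 3 higher (adjusted p = 0.042), were lost likewise (adjusted p = 0.56 and adjusted p = 0.63 with an estimated correlation). Falls were also seen for Saci_1298 (-2.47 ± 0.25), Saci_1290 (-2.15 ± 0.19) and Saci_1701 (-2.05 ± 0.22). Of the ups genes upsA rose (1.37 ± 0.20), upsX fell (-0.77 ± 0.17) and 3 were not called (median -0.11, mean 0.06, camera direction up). Of the ced genes cedA fell (-0.55 ± 0.18), though not without Mut0 replicate 3 (-0.40) or Mut1 replicate 1 (-0.39). Adjusted over the list alone these counts were the same. By edgeR 566 genes were higher and 480 lower.

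At 90 min edgeR called 1 of the 9 ups and ced genes higher and 2 lower than before UV in the mutant. Of the 5 ups genes upsA rose by 1.56 ± 0.20, from 10.1 ± 2.4 to 29.2 ± 3.90 CPM, and upsX fell by 0.79 ± 0.17. The others, upsF (-0.15 ± 0.30), Saci_1494 (-0.45 ± 0.33) and Saci_1497 (-0.12 ± 0.14), were not called, and the median was -0.15, the mean 0.01 and camera's direction down. Of the 4 ced genes cedA fell by 0.93 ± 0.19 and cedB (0.00 ± 0.16), cedA1 (-0.17 ± 0.18) and cedA2 (0.50 ± 0.35) were not called, and camera called neither list (adjusted p = 0.98 and 0.70). The division genes fell, 7 of 8 with a median of -1.79, among them cdvB (-1.92 ± 0.14), cdvC (-1.73 ± 0.15) and Saci_0203 (-2.54 ± 0.17); the counts of these lists were the same adjusted over the list alone. Camera called the division genes (adjusted p = 2.8e-08), the purine genes, 8 of 9 lower (adjusted p = 5.3e-06), and the pyrimidine genes, 10 of 14 lower and 1 higher (adjusted p = 0.015). None of the 3 calls held with an estimated correlation (adjusted p = 0.071, adjusted p = 0.12 and adjusted p = 0.074 with an estimated correlation). Saci_0478 (4.70 ± 0.34), Saci_0477 (3.78 ± 0.37), Saci_0903 (3.40 ± 0.20), Saci_0483 (2.84 ± 0.28) and Saci_1391 (2.62 ± 0.16) had the largest rises named by the rule. The largest falls were those of Saci_1290 (-3.15 ± 0.20), Saci_1193 (-3.10 ± 0.14), Saci_1012 (-2.96 ± 0.20), Saci_1189 (-2.86 ± 0.17) and purS (-2.77 ± 0.23). By edgeR 614 genes were higher and 531 lower.

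Between 45 and 90 min in the mutant, tfb3 rose by 1.27 ± 0.12, Saci_0477 by 1.27 ± 0.27, Saci_1873 by 1.21 ± 0.10, cas7d by 1.20 ± 0.12 and Saci_2112 by 1.18 ± 0.18 (n = 3). The division genes fell, 7 of 8, also adjusted over the list alone, with a median of -1.38 and a camera call that held (adjusted p = 0.0025 with an estimated correlation). Saci_0204 fell by 2.25 ± 0.18, and falls were also called for Saci_0743 (-2.30 ± 0.24), Saci_1012 (-2.19 ± 0.19), Saci_1295 (-2.10 ± 0.27) and Saci_1193 (-2.05 ± 0.13). None of the ups or ced genes was called. Of 11 CRISPR-associated genes 3 rose, with a camera call (adjusted p = 7.9e-05) that was lost (adjusted p = 0.29 with an estimated correlation). By edgeR 123 genes were higher and 119 lower, or 50 and 75 in a fit of only the libraries compared. These counts were 66 and 63 without Mut1 replicate 3 and 218 and 199 without Mut1 replicate 1. The fall of Saci_0451 was not called without Mut1 replicate 2 (-0.78), Mut1 replicate 3 (-0.72), Mut2 replicate 1 (-0.66) or Mut2 replicate 2 (-0.60).

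How much of the UV response the strains had in common was read from comparisons that share no library. At 45 min 375 genes were higher in both strains, where independent lists of those sizes would share 130, and 337 were lower in both, against 110. At 90 min these numbers were 459 against 163 and 411 against 132, and at each time 6 genes were called in opposite directions. Across the 2215 genes the log2 changes of the strains had r = 0.82 and rho = 0.80 at 45 min and r = 0.83 and rho = 0.85 at 90 min; genes are not independent replicates. Saci_0903, Saci_0478, cdvB, Saci_0203 and purS were among the genes called in the same direction in both strains at 90 min.

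**Figure D2:**
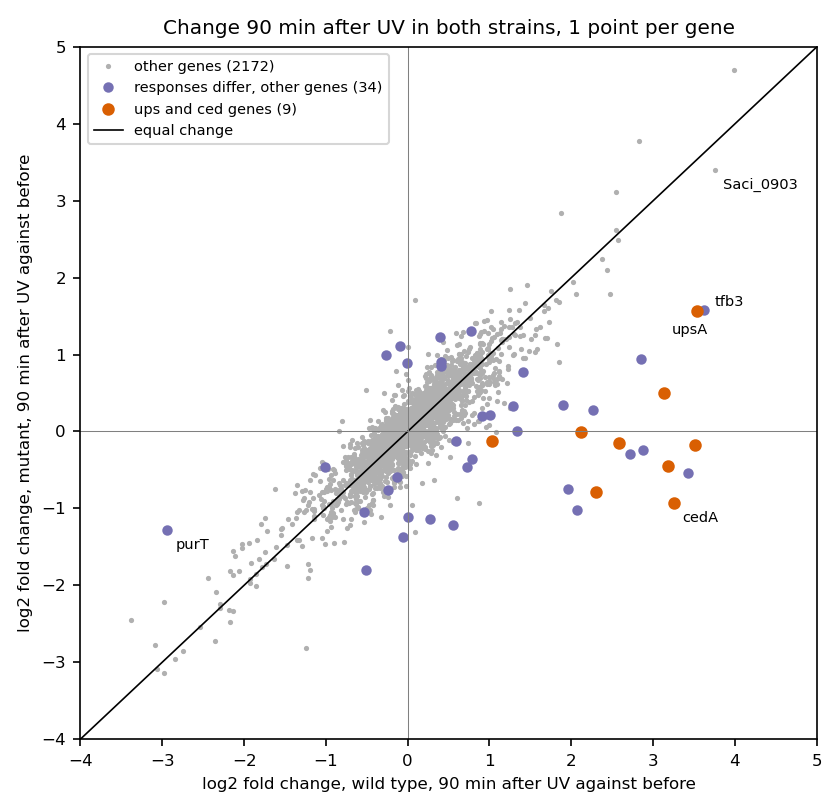
Change at 90 min after UV against before (log2 fold change) in the wild type (horizontal axis) and in the tfb3 insertion mutant (vertical axis); each point is a gene, orange marks the 9 ups and ced genes, purple the other 34 genes whose responses differed and grey the rest. The line marks equal change; the orange points lie below it, with cedA at 3.26 and -0.93.

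The difference of the responses was then tested itself. At 90 min the response was lower in the mutant for all 9 ups and ced genes, most of all for cedA (-4.19 ± 0.26, n = 3, edgeR adjusted p = 3.7e-09), cedA1 (-3.68 ± 0.25), Saci_1494 (-3.63 ± 0.41) and upsX (-3.10 ± 0.24). The others were upsF (-2.73 ± 0.39), cedA2 (-2.63 ± 0.42), cedB (-2.12 ± 0.22), upsA (-1.97 ± 0.26) and Saci_1497 (-1.15 ± 0.19). The counts adjusted over the list alone were again 5 of 5 and 4 of 4, with medians of -2.73 and -3.16, and camera's calls held (adjusted p = 2.1e-04 for ups and adjusted p = 5.5e-05 for ced with an estimated correlation). The other genes named by the rule were Saci_1225 (-3.97 ± 0.23), Saci_1302 (-3.12 ± 0.26), Saci_0667 (-3.00 ± 0.26), Saci_1270 (-2.71 ± 0.33) and tfb3 (-2.04 ± 0.18). The response of nurA, a nuclease of DNA end processing, was lower as well (-1.31 ± 0.21). Its wild-type level did not rise, with 156 ± 14.4 CPM before UV and 150 ± 36.3 CPM at 90 min. In the mutant nurA was at 51.9 ± 2.03 CPM at 90 min. Saci_0197 (-1.99 ± 0.26), Saci_1341 (-1.78 ± 0.28), Saci_0950 (-1.55 ± 0.19), Saci_0474 (-1.33 ± 0.24) and Saci_0497 (-0.95 ± 0.15) were chosen after their values were seen. So was Saci_1171 (-1.19, edgeR adjusted p = 0.032), which shares the symbol arnR with Saci_1180. Of the 34 genes with a lower response, 27 were higher at 90 min than before UV in the wild type and 6 in the mutant. Lower than before UV were 3 of them in the wild type and 12 in the mutant.

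The response at 90 min was higher in the mutant for 9 genes, led by purT (1.66 ± 0.23, adjusted p = 2.2e-04), Saci_1733 (1.26 ± 0.25) and Saci_1734 (1.21 ± 0.29). For purT the fall after UV was smaller in the mutant, from a lower starting level. Camera called the purine genes (adjusted p = 6.9e-04) and the archaellum genes (adjusted p = 0.027), and both calls were lost (adjusted p = 0.35 and adjusted p = 0.54 with an estimated correlation). None of the 8 division genes differed in response (median 0.01, mean 0.00, camera direction down and adjusted p = 0.99); edgeR's estimate for cdvB was 0.01 ± 0.19. In all, edgeR called 9 genes higher and 34 lower, or 13 and 24 with library totals as the only scaling. The higher count was 4 to 8 with a library left out, 14 with the replicate number as a block or only the libraries compared, and 18 by the DESeq2 Wald test. The call of Saci_1734 was lost in 10 of 12 fits with a library left out (lowest 0.98, without Mut2 replicate 2).

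**Figure D3:**
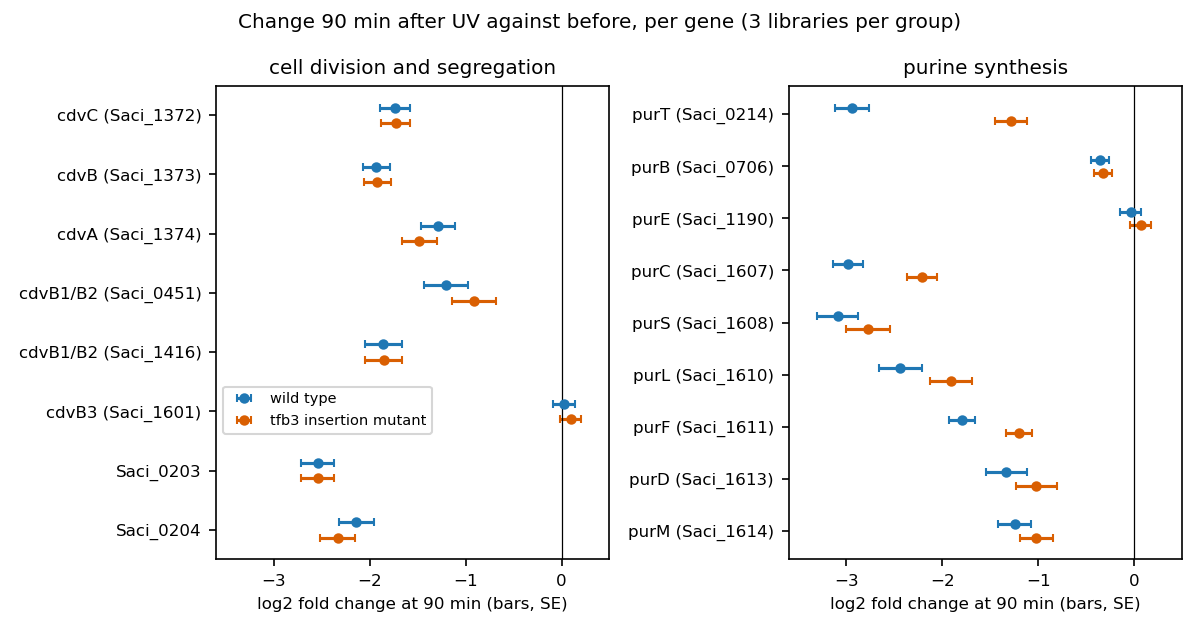
Change at 90 min after UV against before (log2 fold change) of the cell division and segregation genes (left) and the purine synthesis genes (right) in the wild type (blue) and the tfb3 insertion mutant (orange); points are edgeR estimates from 3 replicates per group and bars are their SE. The division genes have near equal values in the strains, while purT is at -2.94 in the wild type and -1.28 in the mutant.

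At 45 min 16 genes differed in response. It was lower in the mutant for tfb3 (-2.25 ± 0.18, n = 3, edgeR adjusted p = 4.6e-07), Saci_2202 (-1.47 ± 0.32), sat (-1.34 ± 0.30), cedA (-1.27 ± 0.25), cedA1 (-1.14 ± 0.25), Saci_2034 (-1.03 ± 0.23) and Saci_1617 (-0.77 ± 0.16). It was higher for 9 genes led by Saci_1733 (1.32 ± 0.25), Saci_1734 (1.31 ± 0.28), purT (1.17 ± 0.23) and purC (0.96 ± 0.21). Saci_0903 (-0.63 ± 0.26, adjusted p = 0.29) and upsA (0.63 ± 0.25, adjusted p = 0.26) were not called. Of 5 ups genes none was called over all genes, and adjusted over the list alone 1 had a higher and 2 had a lower response; of the ced genes 2 of 4 were lower by either adjustment. Camera called the ced, purine, ribosomal protein, histidine and amino acid synthesis lists (adjusted p = 5.4e-04 to 0.0071), and every call was lost (adjusted p = 0.25 to adjusted p = 0.38 with an estimated correlation). The calls, 9 higher and 7 lower, were 5 and 6 with DESeq2 size factors and 9 and 3 with library totals. They were 0 and 2 with only the libraries compared and 26 and 27 by the DESeq2 Wald test. Each gene except tfb3 lost its call without at least 1 library, and the counts ran from 0 and 1 to 45 and 36, the last without Mut1 replicate 1.

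Before UV the mutant already held fewer transcripts of the ups and ced genes. The level of upsA was 95.3-fold lower, 10.1 ± 2.4 against 949 ± 102 CPM (-6.57 ± 0.21, n = 3, edgeR adjusted p = 7.3e-14). Saci_1494 stood at -4.37 ± 0.29, upsF stood at -2.56 ± 0.28, upsX at -1.42 ± 0.17, cedA at -2.07 ± 0.18 and cedB at -1.77 ± 0.16. All 5 ups genes and all 4 ced genes were lower, also adjusted over the list alone, with medians of -2.55 and -1.90 and camera calls that held (adjusted p = 6.4e-04 and adjusted p = 0.012 with an estimated correlation). Saci_0951 (-4.80 ± 0.21), Saci_1302 (-4.06 ± 0.19), Saci_1225 (-2.66 ± 0.16) and Saci_0667 (-2.23 ± 0.18) were lower as well. Among the purine genes 6 of 9 were lower, with a median of -1.10 (adjusted p = 0.035 with an estimated correlation), including purT (-1.88 ± 0.17) and purC (-1.73 ± 0.14). The purD call was lost without WT0 replicate 1 (-0.71), WT0 replicate 2 (-0.53), Mut0 replicate 1 (-0.61) or Mut0 replicate 2 (-0.69).

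Higher in the mutant before UV were sat (Saci_2203), a sulfate adenylyltransferase gene (1.99 ± 0.22), and its neighbours Saci_2202 (1.92 ± 0.23), Saci_2201 (1.69 ± 0.18), Saci_2200 (1.55 ± 0.21) and Saci_2198 (1.34 ± 0.12). Of 7 archaellum genes 2 were higher, also adjusted over the list alone, with a camera call (adjusted p = 0.0072) that was lost (adjusted p = 0.36 with an estimated correlation). None of the division genes differed (median -0.03, mean 0.01, camera direction up). Of the 10 neighbours of tfb3 only Saci_0667 was called (list median 0.08, mean -0.16, camera direction down), and its 3' end overlaps thsB by 4 bp on the opposite strand. By edgeR 116 genes were higher and 185 lower; the higher count was 69 without WT0 replicate 1, and 74 and 76 without Mut0 replicates 1 and 2.

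After UV the same genes were again lower in the mutant. At 45 min upsA was 61.5-fold lower in the mutant (-5.94 ± 0.19, n = 3, edgeR adjusted p = 1.2e-13), Saci_1494 stood at -5.39 ± 0.30, Saci_1302 at -4.88 ± 0.20, Saci_0951 at -4.16 ± 0.19 and Saci_1225 at -3.44 ± 0.16. Higher in the mutant were Saci_1770 (1.33 ± 0.17), Saci_1771 (1.05 ± 0.13), Saci_1772 (1.00 ± 0.12), Saci_2266 (0.99 ± 0.14) and Saci_0944 (0.97 ± 0.12). Saci_0903 was 1.79-fold lower (-0.84 ± 0.18). All ups and ced genes were lower, also adjusted over the list alone, with medians of -2.67 and -2.79 (adjusted p = 5.8e-04 and adjusted p = 0.0015 with an estimated correlation). Of the purine genes 6 of 9 were lower with a camera call (adjusted p = 0.015) that was lost (adjusted p = 0.82 with an estimated correlation). Without Mut1 replicate 2 purF was not called (-0.41), nor was purM without WT1 replicate 3 (-0.41), Mut1 replicate 2 (-0.55) or Mut1 replicate 3 (-0.47). By edgeR 269 genes were higher and 216 lower, 420 and 144 with library totals, and 220 and 248 with DESeq2 size factors. A fit of only the libraries compared gave 42 and 91, and without Mut1 replicate 3 the higher count was 160.

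At 90 min upsA was 374-fold lower in the mutant (-8.54 ± 0.21, n = 3, edgeR adjusted p = 1.4e-15), and Saci_1494 (-8.00 ± 0.33), Saci_1302 (-7.18 ± 0.22), Saci_0951 (-6.71 ± 0.21) and Saci_1225 (-6.63 ± 0.18) followed. The medians of the ups and ced genes were -5.29 and -4.98, with 5 of 5 and 4 of 4 lower, also adjusted over the list alone (adjusted p = 2.9e-05 for each with an estimated correlation). Saci_1770 (1.45 ± 0.18), Saci_1771 (1.07 ± 0.13), Saci_1759 (1.03 ± 0.08), sat (0.98 ± 0.24) and Saci_1758 (0.94 ± 0.12) were higher, sat not without WT2 replicate 1 (0.84). By edgeR 201 genes were higher and 198 lower, or 415 and 133 with library totals. The higher count was 121 to 155 without any of the 6 libraries compared. With library totals the median log2 change over all genes was 0.11 to 0.16, against 0.02 to 0.04 with TMM, in this comparison, in that at 45 min, in the mutant at 90 min and in the 90 min difference of responses. At all 3 times 82 genes were lower and 49 higher in the mutant.

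The authors' deposited tables covered 7 of these comparisons. Their log2 fold changes had the opposite sign and were turned to the direction used here. At an adjusted p under 0.05, 582 genes in them were higher and 580 lower in the wild type at 45 min, and 702 and 702 at 90 min. In the mutant the numbers were 483 and 493, then 579 and 572. They were 326 and 370, 94 and 146, and 182 and 286 for the mutant against the wild type before UV, at 45 min and at 90 min. Of these, 979, 1126, 896, 1033, 292, 239 and 356 were called here in the same direction and 0 in the opposite one. For tfb3 the authors' deposited tables gave 2.41 and 3.50 in the wild type and 0.39 (adjusted p = 0.068) and 1.61 in the mutant.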

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

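The tests of explanations in this part, the other splits of the libraries included, were chosen only after the results were seen; the tests of the differences of responses themselves were planned. Each value listed here is a gene whose change after UV differed between the strains in edgeR's test of the difference itself, given as the mutant response minus the wild-type response (log2, 3 replicates per group).

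At 90 min the ups genes upsX (-3.10), Saci_1494 (-3.63), upsF (-2.73), upsA (-1.97) and Saci_1497 (-1.15) and the ced genes cedA2 (-2.63), cedA (-4.19), cedA1 (-3.68) and cedB (-2.12) rose in the wild type and had a lower response in the mutant. A weaker response of the mutant cultures as a whole is argued against: over 195 other genes with a mean change of at least 2-fold, the median ratio of the mutant to the wild-type change was 0.978 (quartiles 0.790 to 1.16), above the 0.442 that is the highest ratio among the 9. The scaling between libraries is argued against as well, since with library totals all 9 stayed lower with a median of -2.64. So is a lack of reads, since 9 of 9 had at least 10 reads in every mutant library before UV and at 90 min. The lowest count, for cedA2, was 10. For 9 of 9 the intervals of the strains' changes did not overlap. What stays open is a need for intact tfb3, a biological explanation that the design names, beside any other difference that the mutant strain may carry; with 1 mutant strain these were not separated.

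In the mutant tfb3 reads rose by 1.58 at 90 min, and the difference of its responses was -2.25 at 45 min and -2.04 at 90 min. Wild-type cells mixed into the mutant cultures are argued against as the source: tfb3 stood at 39.4% of the wild-type level at 90 min, while the 9 ups and ced genes stood at a median of 2.57% (0.266% to 28.1%). Reads from the parts of the locus beside the insertion cannot be told apart from intact transcripts, because counts cover the whole locus. A candidate explanation is that the promoter of tfb3 is still raised after UV in the mutant and gives transcripts that the insertion interrupts; it was not tested.

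Saci_0667, which lies beside thsB downstream of tfb3, had a response lower in the mutant by -3.00 at 90 min and was already lower before UV (-2.23, 95% interval -2.61 to -1.84). A loss of transcripts reading on from tfb3, which would be antisense to Saci_0667, is argued against, provided that the share reading on stayed the same. In the wild type tfb3 rose by 2.56 at 45 min, so reads from it would have raised Saci_0667 by at least 1.92, while its change was 0.37 (interval 0.01 to 0.72). From 45 to 90 min Saci_0667 rose by 2.34 (interval 1.98 to 2.71) and tfb3 by only 1.06 (0.82 to 1.31), although the changes over 90 min, 2.71 and 3.62, lay closer and alone would not exclude it. What stays open is that Saci_0667 may need intact tfb3 as the ups and ced genes may, or that the strain carries another difference; neither was tested.

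Other genes with a lower response at 90 min were Saci_1225 (-3.97), Saci_1302 (-3.12) and Saci_1270 (-2.71). Those with a higher response were purT (1.66), Saci_1733 (1.26), Saci_1734 (1.21), Saci_1255 (0.90), Saci_1634 (0.83), Saci_2311 (0.54), Saci_0077 (0.53), csa3 (0.49) and Saci_1767 (0.44). At 45 min a lower response was called for Saci_2202 (-1.47), sat (-1.34), cedA (-1.27), cedA1 (-1.14), Saci_2034 (-1.03) and Saci_1617 (-0.77). A higher one was called for Saci_1733 (1.32), Saci_1734 (1.31), purT (1.17), purC (0.96), Saci_1255 (0.88), Saci_1752 (0.78), aceA (0.76), Saci_1710 (0.70) and Saci_2165 (0.66).

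Other splits of the same libraries were tried for each count of called genes. For the 9 comparisons of pairs of groups, 10 splits are too few for a share under 0.05. The real splits, 1 of 10 in each case, gave 1016, 1138 and 346 genes in the wild type, 1046, 1145 and 242 in the mutant, and 301, 485 and 399 between the strains. The highest count of the other splits was 0, or 1 in the last. Each of these other splits mixed the groups compared and so spread their difference within groups. That keeps the counts low, so they do not test chance. For the differences of responses the splits do not test chance, and whether it can be excluded for these counts stays open. The calls of single genes, such as cedA at 90 min (adjusted p = 3.7e-09), rest on edgeR's test and not on splits. Splits that mix the strains unequally carry the difference between the strains, and those with an equal mix spread it within groups. At 45 min 11 of 100 splits gave at least the 16 genes of the real one, with up to 653 in another split. At 90 min 8 of 100 gave at least 43, with up to 113. The large counts point to the strains as a structure of the libraries. At 90 min 7 of 58 splits that mixed the strains unequally reached the real count, while the highest count among 41 splits with an equal mix was 0. At 45 min these were 9 of 51, and 1 of 48 with an equal mix, which gave 39 genes.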

How the results depend on the processing

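Every alternative was planned before the data were examined, and no result reversed. Only gene values and list tests called in the fit of all libraries were followed. None of these could therefore gain a call, and a change of sign was unlikely from the start. The counts of calls have no sign and could only stay or move. Of the counts of calls 223 of 310 stayed within 1.5 times. Of the values of named genes 5323 of 5952 kept their call and 629 were weaker. In the same way 91 of 117 list tests kept theirs (26 weaker, 20 of these with an estimated correlation and 6 by fry). Unless said otherwise the cause was not tested. Requiring a 2-fold change left, by its construction, fewer genes higher and lower. There were 73 and 59 in the wild type at 45 min, 118 and 95 at 90 min, 31 and 29 from 45 to 90 min. In the mutant there were 76 and 83, 111 and 102, and 11 and 29. There were 10 and 45, 3 and 44, and 3 and 51 for the mutant against the wild type before UV, at 45 and at 90 min, and 3 higher in each difference of responses. Fitting only the libraries compared, with fewer residual degrees of freedom, gave 128 and 88 from 45 to 90 min in the wild type, 50 and 75 in the mutant, 42 and 91 for the mutant against the wild type at 45 min. It gave 0 and 2 by edgeR for the 45 min difference of responses, for which the fit of all libraries had 338 genes at an unadjusted p under 0.05. For the 90 min difference 14 were higher. The DESeq2 Wald test called 26 and 27 for the 45 min difference and 18 higher for the 90 min one. Library totals gave 420 and 415 higher in the mutant against the wild type at 45 and 90 min and 3 lower for the 45 min difference, for which DESeq2 size factors gave 5 higher. The rise of tfb3 in the mutant at 45 min was not called with DESeq2 size factors (0.28), the Wald test (0.28) or only the libraries compared (0.28).

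Leaving out 1 library at a time gave 72 to 156 lower genes from 45 to 90 min in the wild type, and 66 to 218 higher and 63 to 199 lower in the mutant. For the mutant against the wild type it gave 69 to 99 higher before UV, 160 to 332 at 45 min and 121 to 155 at 90 min. For the differences of responses it gave 0 to 45 higher and 1 to 36 lower at 45 min and 4 to 8 higher at 90 min. The change of tfb3 in the mutant at 45 min ranged from 0.25 to 0.37 and lost its call in 5 of 6 such fits. The lowest counts from 45 to 90 min came without WT2 replicate 3 and Mut1 replicate 3, and the highest in the mutant without Mut1 replicate 1. The deviations of libraries from their group mean gave no sign of pairing by replicate number, though 3 libraries per group cannot exclude it. Of 45 pairs with the same number 17 were correlated above 0.1, and the values ran from -0.56 to 0.42. Their median was -0.024, against 0.0085 for other numbers, and 7 of 18 libraries correlated best with their own number. With the replicate number as a block, 14 genes were higher in the 90 min difference of responses, and no other count moved by more than 1.5 times. A fit without ribosomal and transfer RNA loci was not run, since the table analysed holds no such locus. Depth limits genes such as Saci_0478, at 1.54 CPM before UV in the wild type.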

Other observations

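The test of the hypothesis in this part was chosen only after the result was seen, and so were the genes from Saci_1731 to Saci_1735, Saci_1872 and Saci_1873, Saci_0476 and Saci_2197 to Saci_2204 that the naming rule did not take. Genes beside cas7d (Saci_1874) fell by 45 min and rose between 45 and 90 min in both strains. Saci_1873 went from 530 ± 18.1 to 201 ± 6.31 and back to 498 ± 32.3 CPM in the wild type (n = 3), with log2 changes of -1.40 at 45 min and -0.09 at 90 min against before UV, and had -1.40 and -0.20 in the mutant. Saci_1872 had -1.51 and -0.26 in the wild type and -1.56 and -0.51 in the mutant, and cas7d fell by 0.79 and 0.90 at 45 min and was at 0.31 and 0.30 at 90 min. These loci follow each other on the chromosome, and edgeR called each fall at 45 min and each rise after it. At 90 min Saci_1872 was still called lower than before UV in the mutant, and cas7d higher in both strains.

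The genes of the Orc1/Cdc6 family moved apart after UV. While Saci_0903 rose, Saci_0722 fell by 1.47 ± 0.12 in the wild type and 1.48 ± 0.12 in the mutant at 90 min, and Saci_0001 rose by 0.43 ± 0.15 and 0.55 ± 0.15. The chromatin gene sac7d fell in both strains at 90 min (-1.22 ± 0.18 and -1.91 ± 0.19; difference of responses -0.69 ± 0.25, not called). The gene dps rose by 1.11 ± 0.17 in the wild type and 0.78 ± 0.17 in the mutant at 90 min, and hsp20 by 1.12 ± 0.17 and 0.72 ± 0.17, while of the 2 loci with the symbol thsA Saci_1401 fell by 0.65 ± 0.13 and 0.84 ± 0.13 and Saci_1203 was not called (0.09 ± 0.26 and -0.05 ± 0.26). Saci_0476, Saci_0477 and Saci_0478, which are neighbours, rose at 90 min in both strains, by 2.55, 2.83 and 3.99 in the wild type and 3.12, 3.78 and 4.70 in the mutant, from under 2 CPM.

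A run of neighbours around sat differed between the strains without UV. Saci_2197 (1.29), Saci_2198 (1.34), Saci_2200 (1.55), Saci_2201 (1.69), Saci_2202 (1.92), sat (1.99) and Saci_2204 (1.56) were higher in the mutant before UV, while Saci_2199 (0.44 ± 0.16) was not called. In the mutant sat went from 41.1 ± 6.86 to 20.0 ± 5.4 CPM at 45 min, and in the wild type from 10.3 ± 0.21 to 12.6 ± 1.91 CPM. Saci_1731 (-1.21), Saci_1732 (-1.33), Saci_1733 (-1.74), Saci_1734 (-2.25) and Saci_1735 (-1.62), also neighbours, were lower in the mutant before UV.

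A hypothesis was that genes with a lower UV response in the mutant also have a lower level there without UV. Of the 34 genes with a lower 90 min response, 17 were lower in the mutant before UV, where 2.84 would be shared by independent lists, and 7 were higher, where 1.78 would be. Both comparisons use the libraries taken before UV, with a sign that works against the overlap of 17 and toward that of 7. Of the 9 genes with a higher 90 min response, 5 were also lower before UV and 0 higher. The shared libraries work toward this overlap of 5, so it cannot decide whether a lower level before UV is particular to lower responses. Whether the same genes depend on tfb3 with and without UV stays open, as a hypothesis found and tested on the same libraries.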
